A study of Homo sapiens with 21 samples.

How the data were processed

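Transcript levels were measured by TempO-Seq in HepG2/C3A cells, a human hepatoma-derived line, grown as a 2D monolayer or as spheroids aged 3, 7, 10, 14, 21 or 28 days, with 3 libraries per group and 21 in all. Per the labels' protocols, total RNA was extracted with a column kit, libraries were made with the assay maker's kit, and the same amount of RNA went into each library. The authors deposited 1 table of raw counts per gene symbol for all libraries; its values are whole numbers with a different total in each library. The submitters' processing notes name bcl2fastq 2.20.422, fastp 0.23.2, STAR 2.7.10b and DESeq2 1.38.0 and the genome build GRCh38.p13, with no role or order for each. How the counts of several detector oligos of 1 gene were combined, and whether probes of abundant genes were attenuated, is not given in the sources used here. A targeted assay reads a short stretch of each transcript, so a level depends on its probe and compares libraries rather than genes, and genes with near-identical copies can share counts. This applies to histone, metallothionein, SAA, ORM, AKR1C, SULT1A and UGT genes, to HSPA1A and HSPA1B, to SLC2A3 and SLC2A14, and to TRIM73, and their single-gene values are uncertain in that respect.

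The table held 19683 gene symbols, of which 3403 were at 0 in all libraries. In 3 symbols a spreadsheet date or a stray point had replaced the gene name; they were left as deposited. No mitochondrially encoded genes with MT- names were in the table. Each column was matched to its library by the sample description in the labels, and no column of any other sample was present. Totals ran from 18760232 to 43443262 counts with a median of 31997292. Counting error limits fold changes that rest on few counts, such as the 6 of CYP3A4 and the 4 of CA9 in the monolayer libraries. Replicate pairs of a group differed by more than sampling noise, with a chi-square per degree of freedom of 5.68 to 29.7 over genes with at least 50 counts in the pair, so no pair looked like repeat deposits of 1 library. Whether the libraries come from separate cultures is not known from this.

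The groups, comparisons, tests, gene lists, alternatives and rule for named genes were fixed before the data were examined. Genes passing filterByExpr with its minimum count of 10 were kept, 12345 genes; the 7338 removed held 0.0108% of the counts. Libraries were scaled by TMM and fitted together in edgeR 4.0.16 (R 4.3.3) with robust quasi-likelihood, a biological coefficient of variation of 9.62%, 14 residual and 18.0 prior degrees of freedom. The comparisons were each spheroid day with the monolayer, each day with the day before it, Day 28 with Day 3, and an F test of any change among the 6 spheroid days. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. The SE of a log2 fold change was its absolute value divided by the square root of the F statistic. Fold changes come from the fit, and levels are CPM on TMM-scaled library sizes. Principal components used log2 CPM with a prior count of 2.

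The 36 gene lists came from textbook knowledge and hold 778 genes with no repeats. The table had 777 of these, 2 under an older symbol; H19 was the gene not in it, and 665 were tested. The 34 lists with at least 5 tested genes were tested by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 in the 3 main comparisons (Day 3 and Day 28 against the monolayer, and Day 28 against Day 3), with Benjamini-Hochberg adjustment over these 102 tests. Every median of a called list had the sign of its test. Counts of called genes adjusted over the list alone were the same as those over all genes tested in 91 of the 102 tests and differed by at most 1 gene in the other 11. With a correlation estimated from the data, 4 of 20 lists called at Day 3, 9 of 21 at Day 28 and 4 of 16 between Day 28 and Day 3 were still called, and the text gives the adjusted p where the call was lost. Fry, which asks whether the genes of a list move one way on balance and compares them with no other genes, called 31, 31 and 29 lists.

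For each main comparison the rule named the 5 genes with the largest rise and the 5 with the largest fall among called genes with a mean of at least 10 CPM and no overlap between the groups' libraries, the 2 members of each called list that changed most in its direction, 1 that changed most in the other direction where at least 2 did, and 12 genes fixed in advance. Other comparisons named 3 genes in each direction. The rule gave 68, 69 and 57 genes in the main comparisons, more than can be given in full, so they are printed as a log2 fold change with its SE, grouped by list. Some genes that the rule named are not reported here. Of 171 named genes 166 had a location in GENCODE 29 on GRCh38, matched by symbol, since the table holds no coordinates. XIST and Y-linked genes were left out.

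For comparisons that share libraries, unchanged groups were simulated 20 times from each gene's mean over all libraries and its estimated dispersion. The gene tests were checked on simulated counts for 12097 genes, with 200 genes changed and the mitosis list raised 2-fold at Day 28. For Day 28 against the monolayer edgeR recovered 59.7% of genes changed by 1.5-fold, 76.1% of those changed by 2-fold and 87.9% of those changed by 4-fold, and 9.09% of its calls were unchanged genes; where nothing was changed it made 1 call. Camera called the changed list in both tests of it and 2 other tests of the 102. The simulated genes were drawn independently, so this check does not test the preset inter-gene correlation. Few genes were changed in it, while 73.4% of the genes tested were called for Day 28 against the monolayer. Its shares of recovered genes and of false calls, and how TMM scaling behaves, need not hold for these data. Alternatives were RLE size factors in edgeR, library size alone, no filter on low counts, DESeq2 1.42.0, a 2-fold minimum, the replicate number as a block, a fit of only the groups compared, and leaving out each library. Labels give no batch, plate, lane or date, so no batch term could be fitted.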

Results

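The data are gene counts from 21 libraries of HepG2/C3A, a human hepatoma-derived liver cell line, measured by TempO-Seq, an assay in which pairs of gene-specific detector oligos are ligated on RNA and sequenced. The cells grew either as a flat layer on plastic (2D monolayer) or as 3D spheroids that were formed in low-attachment plates and then kept in a rotating bioreactor. Spheroids were collected at Days 3, 7, 10, 14, 21 and 28, which gives 7 groups of 3 libraries. The libraries held 18760232 to 43443262 counts, with a median of 31997292, and the shallowest was Day 28 replicate 1. The design asks how the transcriptome changed as spheroids formed and were maintained. Levels below are CPM, counts scaled by library size, as mean ± SD over n = 3 libraries, and log2 fold changes are given ± SE. The labels call the replicates biological but do not say whether they came from separate cultures, so p-values measure the spread between these samples. The fit shares 1 estimate of spread per gene over all groups, although replicate pairs differed more at Days 21 and 28 than at Day 3. SEs and p-values of the late days may therefore be too small.

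The monolayer stood apart from every spheroid group, and spheroids of Days 3, 7 and 10 stood apart from those of Days 14, 21 and 28. The first principal component held 56.25% of the variance and placed the monolayer at -137.9 ± 1.18 (SD, n = 3), against 42.34 ± 1.37 at Day 3, 47.4 ± 1.46 at Day 10, 4.063 ± 7.28 at Day 14 and -7.593 ± 2.52 at Day 28. The second component held 18.92% and placed the monolayer at 29.15 ± 0.789. It fell from 26.31 ± 1.71 at Day 10 to -27.34 ± 5.12 at Day 14 and -53.94 ± 0.877 at Day 28. Of 12345 genes tested, 9402 changed at some time among the 6 spheroid days by the edgeR F test, 2826 of them by at least 2-fold in one of its contrasts. The count of changed genes against the monolayer was 9627 at Day 3, 9719 at Day 7, 9618 at Day 10, 9184 at Day 14, 9176 at Day 21 and 9058 at Day 28. Between consecutive days it was 2393 from Day 3 to Day 7, 3382 from Day 7 to Day 10, 5967 from Day 10 to Day 14, 3289 from Day 14 to Day 21 and 2964 from Day 21 to Day 28.

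**Figure D1:**
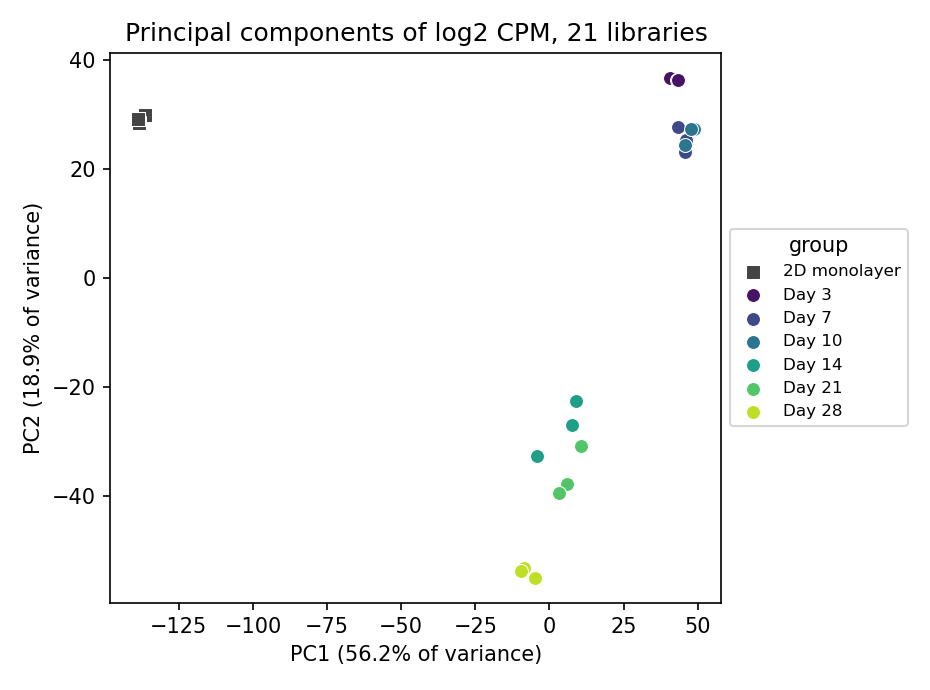
Principal components of log2 CPM of the 21 libraries, with PC1 on the x axis, PC2 on the y axis and 1 point per library coloured by group. The monolayer libraries lie near -137.9 on PC1, and Days 14, 21 and 28 lie below 0 on PC2 while the other groups lie above 0.

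**Figure D2:**
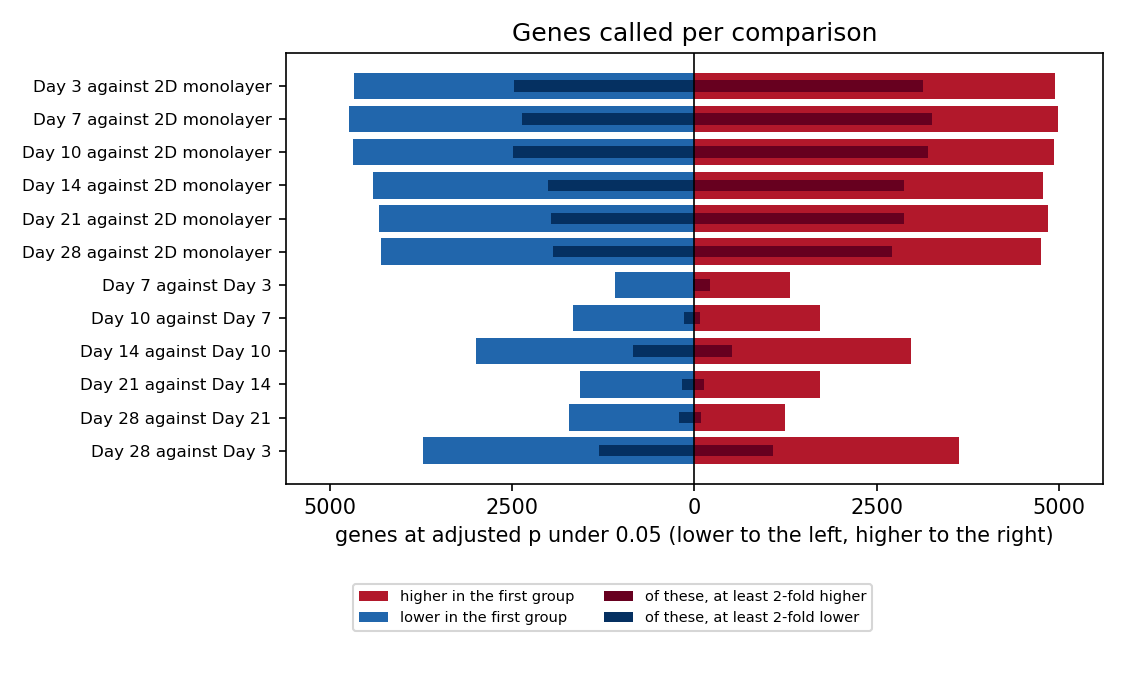
Number of genes higher and lower at adjusted p under 0.05 in each of the 12 comparisons (edgeR), lower genes drawn to the left and higher genes to the right of 0. Among consecutive days, the step from Day 10 to Day 14 has the most genes, 2968 higher and 2999 lower.

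At Day 3, genes of the cell cycle, of plasma proteins and of lipid metabolism were higher in spheroids than in the monolayer, and genes of the ATF4 amino acid response, immediate early genes and YAP targets were lower. With an estimated correlation the lists for mitosis, DNA replication, plasma proteins, cholesterol and YAP targets did not pass (adjusted p = 0.0613, 0.105, 0.0613, 0.0905 and 0.0523). MKI67, the proliferation marker Ki-67, stood at 159 ± 5.2 CPM in Day 3 spheroids and 3.31 ± 1.3 in the monolayer, a 49.6-fold difference. ALB, which encodes albumin, rose from 1860 ± 84 to 11500 ± 570 CPM, and AFP, the fetal plasma protein alpha-fetoprotein, from 3730 ± 290 to 12200 ± 180. AREG, a ligand of the epidermal growth factor receptor, fell from 2510 ± 180 to 18.3 ± 8.1 CPM. ASNS, asparagine synthetase, fell from 541 ± 43 to 24.3 ± 0.75. In GRCh38 coordinates (GENCODE 29), ALB spans chromosome 4, 73397114 to 73421412, and AFP lies next to it at 73431138 to 73456174, both on the plus strand. MKI67 spans chromosome 10, 128096659 to 128126385, on the minus strand.

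All 24 measured mitosis genes rose, with a median log2 fold change of 4.74 (camera, adjusted p = 1.83e-17; adjusted p = 0.0613 with an estimated correlation). KIF20A, a kinesin of cell division, rose by 5.69 ± 0.24. All 29 DNA replication genes rose as well, with a median of 3.23 (adjusted p = 2.46e-13, or adjusted p = 0.105 with an estimated correlation), led by RRM2, a subunit of ribonucleotide reductase, at 5.51 ± 0.32 and by EXO1, a DNA exonuclease, at 5.45 ± 0.19. Genes with the largest rises included the histone gene H2AC4 (5.80 ± 0.31) and the kinetochore genes CENPM (5.72 ± 0.28) and SPC24 (5.71 ± 0.30). LCN15, a lipocalin, rose most, by 6.49 ± 0.54, and ERP27, a protein of the endoplasmic reticulum, by 5.77 ± 0.15.

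Of 29 genes for hepatocyte plasma proteins, 26 rose and 1 fell, with a median of 1.98 (adjusted p = 9.8e-11; adjusted p = 0.0613 with an estimated correlation), including APOC3 (4.55 ± 0.11) and CP, which encodes ceruloplasmin (3.63 ± 0.085). Fatty acid oxidation and ketogenesis had 22 of 25 genes higher and none lower (median 1.66, adjusted p = 2.62e-07). Among them were EHHADH of peroxisomal oxidation at 4.92 ± 0.10 and FABP1, the liver fatty acid binding protein, at 4.15 ± 0.15. Fatty acid and triglyceride synthesis had 17 of 20 higher and 2 lower (median 2.13, adjusted p = 4.47e-06). The list included the acetyl-CoA carboxylase ACACB at 4.19 ± 0.13 and FASN, fatty acid synthase, at 3.63 ± 0.092. Cholesterol synthesis and uptake had 21 of 23 higher and 1 lower (median 2.31, adjusted p = 7.79e-10; adjusted p = 0.0905 with an estimated correlation), with TM7SF2 at 4.14 ± 0.13 and FDPS at 3.66 ± 0.17. In the urea cycle and amino acid catabolism list, 15 of 20 rose and 4 fell (median 1.75, adjusted p = 0.00492; adjusted p = 0.0523 with an estimated correlation). Its members included AGXT at 4.19 ± 0.13, GLS2 at 3.01 ± 0.16 and TAT, tyrosine aminotransferase, at -2.00 ± 0.10. CPS1, the first enzyme of the urea cycle, rose by 2.21 ± 0.16, and HNF4A, a hepatocyte transcription factor, by 1.34 ± 0.11.

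Phase I drug metabolism had 11 of 15 genes higher and 2 lower (median 2.42, adjusted p = 0.00347; adjusted p = 0.0535 with an estimated correlation). Among them were FMO5 at 2.65 ± 0.093 and EPHX1, an epoxide hydrolase, at 1.98 ± 0.068. Phase II conjugation had 10 of 16 higher and 1 lower (median 0.96, adjusted p = 0.008; adjusted p = 0.131 with an estimated correlation), with the sulfotransferase SULT1A1 at 3.12 ± 0.10 and the glutathione transferase GSTA4 at 2.98 ± 0.12. Hepatic transporters had 11 of 15 higher and 3 lower (median 1.72, adjusted p = 0.0163; adjusted p = 0.104 with an estimated correlation). Examples were SLC22A9 at 3.77 ± 0.16 and ABCC6 at 3.24 ± 0.088, while ABCB1, a drug efflux pump, fell by 1.78 ± 0.061. CYP3A4, a main drug-oxidizing cytochrome P450, was near the detection limit, with 1.64 ± 0.21 CPM at Day 3 and 0.0556 ± 0.052 in the monolayer (4.62 ± 0.60). CYP7A1, the rate-limiting enzyme of bile acid synthesis, stood at 0.151 ± 0.039 against 0.444 ± 0.17 CPM (-1.47 ± 0.57, adjusted p = 0.02), and this call was lost without monolayer replicate 1 (adjusted p = 0.0837) or Day 3 replicate 3 (adjusted p = 0.0632). CYP1A2 had 2 counts in all libraries together and was not tested. Acute phase proteins had 8 of 14 higher and 3 lower (median 1.30, adjusted p = 0.0331; adjusted p = 0.191 with an estimated correlation). Its members included haptoglobin HP at 4.02 ± 0.12, SAA4 at 3.77 ± 0.11 and LCN2 at -4.45 ± 0.13. Fetal liver and progenitor genes had 10 of 12 higher and 1 lower (median 0.94, adjusted p = 0.0201; adjusted p = 0.0613 with an estimated correlation), with the imprinted genes PEG10 at 2.51 ± 0.12 and DLK1 at 2.40 ± 0.13. Of 8 metallothionein-list genes 7 rose (median 2.42, adjusted p = 0.00726; adjusted p = 0.193 with an estimated correlation), MT1G by 5.28 ± 0.35 and MT1M by 3.73 ± 0.24.

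Lower at Day 3 were 21 of 25 genes of the ATF4 amino acid response, with 3 higher (median -2.57, adjusted p = 1.62e-12), including PPP1R15A, a phosphatase subunit of the stress response, at -4.60 ± 0.084 and ASNS at -4.47 ± 0.075. PSPH, the last enzyme of serine synthesis, went the other way at 2.95 ± 0.11. Of 19 immediate early genes 18 fell and none rose (median -3.18, adjusted p = 1.67e-09), among them DUSP5, a phosphatase of ERK kinases, at -6.74 ± 0.36 and the transcription factor EGR1 at -5.31 ± 0.14. YAP and TEAD targets had 16 of 17 lower and none higher (median -2.22, adjusted p = 9.24e-06; adjusted p = 0.0523 with an estimated correlation). The list included AXL, a receptor tyrosine kinase, at -5.70 ± 0.30 and ANKRD1 at -4.98 ± 0.19. Heat shock genes had 16 of 18 lower and 2 higher (median -1.11, adjusted p = 1.12e-06; adjusted p = 0.0613 with an estimated correlation). Examples were HSPA1A at -5.22 ± 0.29, HSPA1B at -3.06 ± 0.089 and the mitochondrial cochaperonin HSPE1 at 0.55 ± 0.081. Chaperones of the endoplasmic reticulum had 16 of 20 lower and 1 higher (median -0.83, adjusted p = 1.96e-04; adjusted p = 0.134 with an estimated correlation), with DNAJB9 at -3.72 ± 0.099 and SEL1L at -2.24 ± 0.095. The NRF2 antioxidant response had 14 of 24 lower and 8 higher (median -0.70, adjusted p = 0.00726; adjusted p = 0.339 with an estimated correlation). Among them were sulfiredoxin SRXN1 at -3.51 ± 0.096, GCLC of glutathione synthesis at -2.93 ± 0.073 and heme oxygenase HMOX1 at 2.29 ± 0.11.

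Actin cytoskeleton and focal adhesion genes had 17 of 29 lower and 7 higher (median -0.47, adjusted p = 0.0338; adjusted p = 0.134 with an estimated correlation). The list included TAGLN at -3.08 ± 0.18 and CAPG at 1.35 ± 0.14. ACTB, beta-actin, rose by 0.63 ± 0.076. The genes with the largest falls were ATP6V0D2, a proton pump subunit, at -7.21 ± 0.36, the receptor GPR83 at -7.15 ± 0.32, RGCC at -7.12 ± 0.41, AREG at -7.07 ± 0.58 and GPRC5A at -7.02 ± 0.39. VEGFA, the endothelial growth factor, fell by 1.73 ± 0.063 while CA9, a hypoxia-induced carbonic anhydrase near the detection limit, stood at 1.20 ± 0.25 against 0.0396 ± 0.038 CPM (4.71 ± 0.70). CDKN1A, the cell cycle inhibitor p21, stood at 1.47 ± 0.31 against 3.25 ± 0.53 CPM (-1.15 ± 0.34). In this comparison 4955 genes were higher and 4672 lower by edgeR, and scaling by library size alone gave 5697 higher and 3919 lower. Every named gene that was tested passed, with the highest adjusted p at 0.02 for CYP7A1. The actin list no longer passed with scaling by library size alone (median -0.26, adjusted p = 0.0637).

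At Day 28 the spheroids still had more plasma protein, drug metabolism and cell cycle transcripts than the monolayer, and fewer cytoskeletal, YAP target and immediate early transcripts. With an estimated correlation the lists for mitosis, DNA replication and phase II did not pass (adjusted p = 0.184, 0.46 and 0.0523). FGA, a fibrinogen chain, rose from 70.9 ± 5.9 CPM in the monolayer to 3170 ± 330 at Day 28 (5.48 ± 0.099), and FGG from 82.4 ± 5.7 to 2620 ± 230 (4.99 ± 0.080). ALB stood at 8710 ± 1800 CPM (2.23 ± 0.15 against the monolayer) and AFP at 10200 ± 3000 (1.45 ± 0.15). HNF4A was higher by 1.81 ± 0.11 and CPS1 by 1.77 ± 0.16. MKI67 was 7.96-fold above the monolayer, at 25.4 ± 2.8 CPM. The fibrinogen genes lie together on chromosome 4, FGB at 154562956 to 154571086 on the plus strand, FGA at 154583126 to 154590766 and FGG at 154604134 to 154612967 on the minus strand.

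Of the 29 plasma protein genes, 28 rose and 1 fell at Day 28 (median 2.23, adjusted p = 2.34e-23). In the urea cycle list 16 of 20 rose and 2 fell (median 1.64, adjusted p = 5.88e-06), with AGXT at 4.69 ± 0.13, the histidine ammonia-lyase gene HAL at 2.95 ± 0.17 and SLC25A13 at -0.43 ± 0.065. Acute phase proteins had 11 of 14 higher and 1 lower (median 1.59, adjusted p = 4.32e-07). Its members included HP at 4.43 ± 0.12 and ORM1 at 2.56 ± 0.067. Phase I genes had 11 of 15 higher and none lower (median 2.16, adjusted p = 2.08e-04). Among them were FMO5 at 2.91 ± 0.093 and the carboxylesterase CES2 at 2.16 ± 0.064. Fatty acid oxidation had 23 of 25 higher and 2 lower (median 1.22, adjusted p = 4.04e-07), with FABP1 at 4.0 ± 0.15, EHHADH at 3.45 ± 0.10 and ETFA at -0.51 ± 0.066. Hepatocyte transcription factors had 15 of 20 higher and 3 lower (median 0.94, adjusted p = 0.00726). Examples were CEBPA at 2.62 ± 0.082, the bile acid receptor NR1H4 at 2.30 ± 0.10 and FOXA2 at -1.37 ± 0.13. Phase II genes had 12 of 16 higher and none lower (median 1.97, adjusted p = 2.75e-04; adjusted p = 0.0523 with an estimated correlation). Its members included GSTA4 at 3.76 ± 0.12 and SULT1A1 at 2.21 ± 0.099.

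Hepatic transporters had 10 of 15 higher and 5 lower at Day 28 (median 1.98, adjusted p = 0.00167; adjusted p = 0.0521 with an estimated correlation), with SLC22A9 at 5.67 ± 0.15, the bile acid exporter subunit SLC51A at 4.32 ± 0.20 and ABCB1 at -1.66 ± 0.060. Bile acid synthesis had 10 of 12 higher and 2 lower (median 1.57, adjusted p = 0.0134; adjusted p = 0.112 with an estimated correlation). The list included SLC27A5 at 2.22 ± 0.14, AKR1D1 at 2.06 ± 0.099, CYP7A1 at 1.61 ± 0.46 and AKR1C4 at -2.28 ± 0.089. Cholesterol synthesis had 19 of 23 higher and 1 lower (median 0.81, adjusted p = 0.00287; adjusted p = 0.339 with an estimated correlation). An example was EBP at 1.47 ± 0.18. Fatty acid and triglyceride synthesis had 15 of 20 higher and 2 lower (median 1.44, adjusted p = 0.00218; adjusted p = 0.0999 with an estimated correlation), with GPAM at 3.32 ± 0.15, DGAT1 at 2.16 ± 0.077 and AGPAT2 at -1.71 ± 0.13. All 24 mitosis genes were higher (median 2.63, adjusted p = 5.86e-08; adjusted p = 0.184 with an estimated correlation), TOP2A by 3.13 ± 0.22 and MKI67 by 2.99 ± 0.21. DNA replication had 23 of 29 higher and 2 lower (median 1.39, adjusted p = 0.00297; adjusted p = 0.46 with an estimated correlation). Among them were MCM10 at 2.50 ± 0.25 and CDT1 at 2.08 ± 0.11. The fetal liver list had 10 of 12 higher and 1 lower (median 0.91, adjusted p = 0.028; adjusted p = 0.0653 with an estimated correlation). The list included the fetal growth factor IGF2 at 1.75 ± 0.12. The remaining genes with the largest rises were DEPTOR, an inhibitor of mTOR kinase, at 6.62 ± 0.29, HS6ST2 at 5.78 ± 0.42 with a wide spread (136 ± 82 CPM), and G6PC, glucose 6-phosphatase, at 5.50 ± 0.31.

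Actin and focal adhesion genes had 23 of 29 lower and 3 higher at Day 28 (median -1.12, adjusted p = 3.71e-06), with TAGLN2 at -4.07 ± 0.27, TAGLN at -3.73 ± 0.19, ACTB at -0.77 ± 0.077 and CALD1 at 0.63 ± 0.062. YAP and TEAD targets had 13 of 17 lower and 2 higher (median -1.58, adjusted p = 3.83e-06). Its members included ANKRD1 at -6.77 ± 0.21 and AXL at -5.67 ± 0.30. Of 19 immediate early genes 18 fell and none rose (median -2.69, adjusted p = 7.42e-09). Among them were DUSP5 at -6.54 ± 0.36 and KLF4 at -4.39 ± 0.24. Heat shock genes had 15 of 18 lower and 1 higher (median -0.99, adjusted p = 1.66e-07; adjusted p = 0.0523 with an estimated correlation), with HSPA1A at -3.66 ± 0.26 and HSPA1B at -3.14 ± 0.089. The NRF2 list had 16 of 24 lower and 3 higher (median -0.87, adjusted p = 1.99e-05; adjusted p = 0.148 with an estimated correlation). Examples were AKR1C1 at -2.77 ± 0.095, SRXN1 at -2.45 ± 0.091 and HMOX1 at 0.56 ± 0.12. The p53 response had 15 of 24 lower and 5 higher (median -0.49, adjusted p = 0.033; adjusted p = 0.0613 with an estimated correlation). Its members included GDF15 at -2.95 ± 0.079, AEN at -1.79 ± 0.10, CDKN1A at -2.76 ± 0.39 and BAX at 0.60 ± 0.069. The ATF4 list went both ways, with 13 of 25 lower and 9 higher (median -0.25, adjusted p = 0.038; adjusted p = 0.0727 with an estimated correlation). Its members PPP1R15A at -3.30 ± 0.079 and TRIB3 at -2.24 ± 0.10 were lower and PSPH was higher at 2.93 ± 0.11. TRIB3, a pseudokinase induced by ATF4 on chromosome 20, 362835 to 397559, stood at 35300 ± 2100 CPM in the monolayer and 7490 ± 1400 at Day 28.

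The largest falls at Day 28 were in AHNAK2 (-7.34 ± 0.39), AREG (-7.06 ± 0.59), EREG, another ligand of the epidermal growth factor receptor (-6.91 ± 0.44), ATP6V0D2 (-6.86 ± 0.36) and ANKRD1. VEGFA stood at 308 ± 8.2 CPM against 493 ± 25 (-0.68 ± 0.061). CYP3A4 stood at 0.43 ± 0.23 CPM (2.65 ± 0.71) and CA9 at 0.28 ± 0.14 CPM (2.61 ± 0.82), both at few counts. By edgeR 4756 genes were higher and 4302 lower, and scaling by library size alone gave 5661 higher and 3428 lower. Every named gene that was tested passed, with the highest adjusted p at 0.0054 for CA9. The ATF4 list no longer passed with scaling by library size alone (median -0.03, adjusted p = 0.0512) or without Day 28 replicate 2 (adjusted p = 0.0625).

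**Figure D3:**
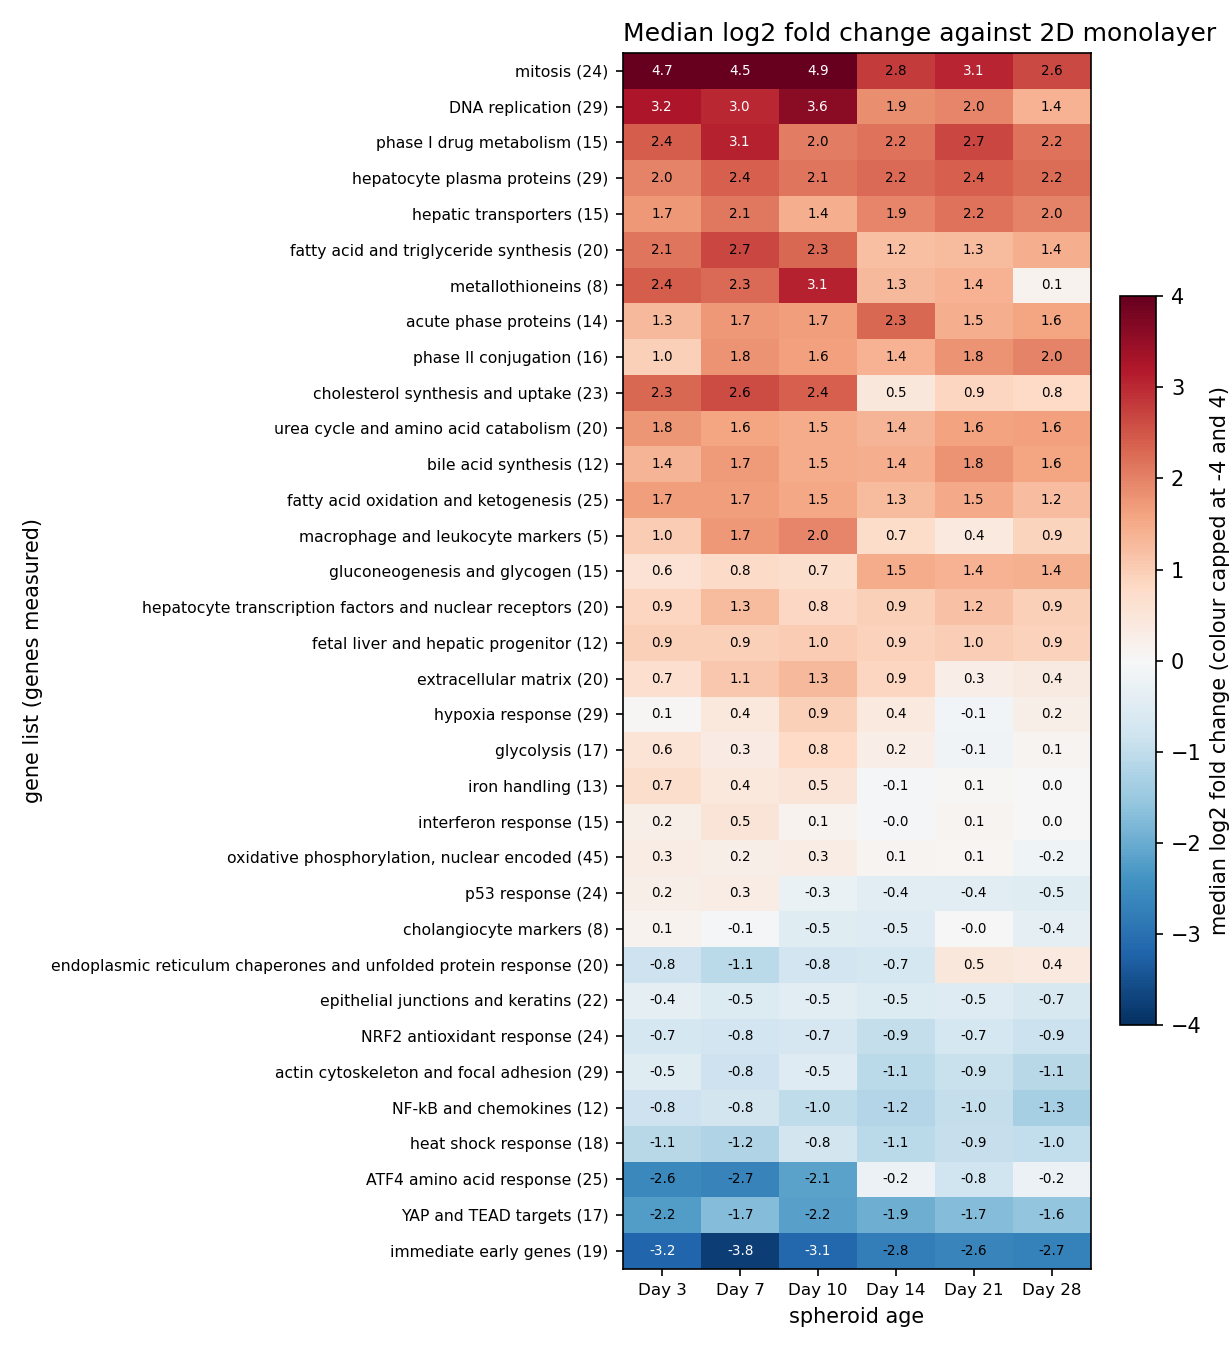
Median log2 fold change against the 2D monolayer of each gene list (rows, with the number of genes measured) at each spheroid day (columns), coloured from blue for lower to red for higher. Mitosis has a median of 4.74 at Day 3 and 2.63 at Day 28, and the ATF4 amino acid response has -2.57 at Day 3 and -0.25 at Day 28.

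Between Day 3 and Day 28, cell cycle, sterol synthesis and metallothionein genes fell in the spheroids, while genes of the ATF4 response and chaperones of the endoplasmic reticulum rose. The list tests of the falls did not pass with an estimated correlation (adjusted p = 0.0535 for mitosis, 0.0523 for DNA replication, 0.0613 for cholesterol and 0.105 for metallothioneins). MKI67 fell from 159 ± 5.2 to 25.4 ± 2.8 CPM. ASNS rose from 24.3 ± 0.75 to 185 ± 9.2, and DDIT3, a transcription factor of the stress response, from 14.2 ± 1.2 to 118 ± 7.3. IGFBP1, an insulin-like growth factor binding protein made by liver, rose from 189 ± 4.2 to 4900 ± 180. ALB stood at 11500 ± 570 at Day 3 and 8710 ± 1800 at Day 28 (-0.40 ± 0.14, adjusted p = 0.023), and this call was lost without Day 3 replicate 2 or 3 or Day 28 replicate 2 or 3, with log2 fold changes of -0.23 to -0.38 and adjusted p from 0.0748 to 0.162. AFP did not pass (-0.26 ± 0.15, adjusted p = 0.14), and passed at -0.51 without Day 28 replicate 1 (adjusted p = 2.89e-05) and at -0.24 with no filter on low counts (adjusted p = 0.00114).

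Of 25 ATF4 response genes 23 rose and none fell (median 1.86, adjusted p = 3.75e-26), DDIT3 by 3.05 ± 0.11 and ASNS by 2.92 ± 0.071. Chaperones of the endoplasmic reticulum had 19 of 20 higher and none lower (median 1.37, adjusted p = 1.42e-19), with SEL1L at 2.26 ± 0.096 and HYOU1 at 2.16 ± 0.086. Acute phase proteins had 11 of 14 higher and 3 lower (median 0.79, adjusted p = 6.57e-05). The list included LCN2 at 1.93 ± 0.13 and SERPINA3 at 1.63 ± 0.23. Plasma proteins had 15 of 29 higher and 11 lower (median 0.20, adjusted p = 3.87e-04; adjusted p = 0.245 with an estimated correlation). Examples were A1BG at 3.03 ± 0.071, ITIH3 at 2.72 ± 0.15 and transferrin TF at -0.99 ± 0.16. Immediate early genes had 11 of 19 higher and 2 lower (median 0.47, adjusted p = 0.0211; adjusted p = 0.215 with an estimated correlation), with MYC at 1.17 ± 0.066, DUSP1 at 1.16 ± 0.091 and IER3 at -0.70 ± 0.13. The largest rises were in KLHDC7B (5.66 ± 0.19), the transporter SLC17A2 (5.17 ± 0.10), HAL (4.91 ± 0.20), IGFBP1 (4.70 ± 0.089) and GPR83 (3.86 ± 0.32). CYP7A1 rose by 3.08 ± 0.52 at few counts, VEGFA by 1.06 ± 0.062 and HNF4A by 0.47 ± 0.11.

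All 29 DNA replication genes fell (median -2.15, adjusted p = 1.32e-21; adjusted p = 0.0523 with an estimated correlation), RRM2 by 4.29 ± 0.30 and the thymidine kinase TK1 by 3.84 ± 0.30. All 24 mitosis genes fell (median -2.23, adjusted p = 4.3e-19; adjusted p = 0.0535 with an estimated correlation), MKI67 by 2.64 ± 0.17 and the kinase gene AURKB by 2.63 ± 0.22. Of 23 cholesterol genes 21 fell and none rose (median -1.21, adjusted p = 6.3e-12; adjusted p = 0.0613 with an estimated correlation), LSS by 2.17 ± 0.22 and IDI1 by 2.12 ± 0.082. Fatty acid and triglyceride synthesis had 13 of 20 lower and 3 higher (median -0.85, adjusted p = 1.89e-04; adjusted p = 0.0613 with an estimated correlation). Among them were AGPAT2 at -2.39 ± 0.13 and FASN at -2.06 ± 0.086. Glycolysis had 14 of 17 lower and 2 higher (median -0.72, adjusted p = 0.00266; adjusted p = 0.134 with an estimated correlation). The list included PGAM1 at -1.47 ± 0.082 and PFKL at -1.08 ± 0.15. Metallothioneins had 7 of 8 lower and 1 higher (median -2.73, adjusted p = 2.84e-04; adjusted p = 0.105 with an estimated correlation), with MT1M at -3.48 ± 0.24 and MT2A at -3.15 ± 0.28.

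Actin and focal adhesion genes had 18 of 29 lower and 2 higher from Day 3 to Day 28 (median -0.61, adjusted p = 0.00179; adjusted p = 0.0523 with an estimated correlation). Its members included ACTB at -1.39 ± 0.078 and the integrin ITGAV at -0.89 ± 0.064. Nuclear-encoded oxidative phosphorylation had 26 of 45 lower and 4 higher (median -0.36, adjusted p = 0.00726; adjusted p = 0.339 with an estimated correlation). Among them were COX7A2 at -1.13 ± 0.093, NDUFA1 at -0.99 ± 0.073 and NDUFS4 at 0.49 ± 0.060. Iron handling had 9 of 13 lower and 1 higher (median -0.92, adjusted p = 0.0272; adjusted p = 0.104 with an estimated correlation), with TMPRSS6, a protease that restrains hepcidin, at -2.90 ± 0.19 and ID1 at -2.77 ± 0.20. Cholangiocyte markers had 5 of 8 lower and 1 higher (median -0.72, adjusted p = 0.005). Examples were ANXA4 at -2.06 ± 0.11 and SPP1, osteopontin, at -1.38 ± 0.18. The extracellular matrix list had 13 of 20 lower and 3 higher (median -0.74, adjusted p = 0.0369; adjusted p = 0.134 with an estimated correlation). Its members included LAMA5 at -1.61 ± 0.21, AGRN at -1.60 ± 0.084 and fibronectin FN1 at 0.91 ± 0.11, and it no longer passed without Day 28 replicate 1 (median -0.64, adjusted p = 0.0912).

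The largest falls were in LCN15 (-6.18 ± 0.53), the calcium-binding genes S100A4 (-5.42 ± 0.31) and S100A3 (-4.35 ± 0.27), H2AC4 (-4.37 ± 0.29) and FAM111B (-4.32 ± 0.25). CYP3A4 fell by 1.97 ± 0.46, CA9 by 2.10 ± 0.54 and CDKN1A by 1.61 ± 0.40, all at few counts. By edgeR 3636 genes were higher and 3727 lower at Day 28 than at Day 3, and the tested named genes other than AFP passed, with the highest adjusted p at 0.023 for ALB. CPS1 fell by 0.44 ± 0.15 (adjusted p = 0.01), a call lost without Day 3 replicate 1, Day 28 replicate 1 or Day 28 replicate 3 (adjusted p = 0.0827, 0.0657 and 0.0697).

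**Figure D4:**
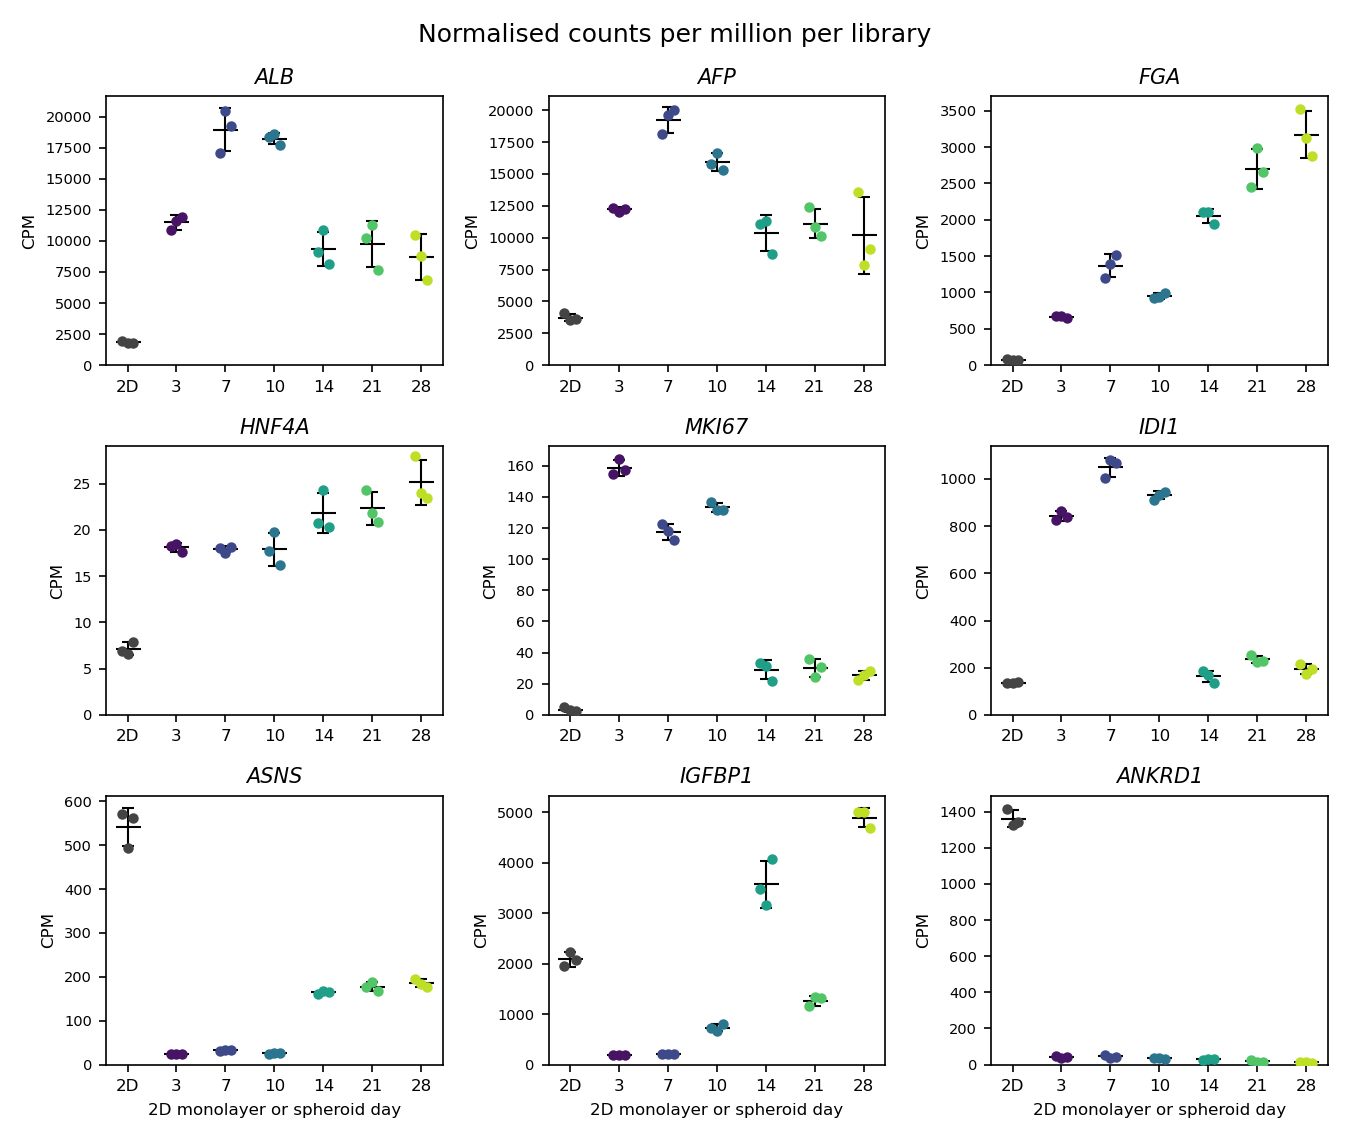
Level in CPM (y axis, linear from 0) of single genes in the 2D monolayer and at each spheroid day (x axis). Points are libraries and bars are mean ± SD of 3; MKI67 goes from 3.31 in the monolayer to 159 at Day 3 and 25.4 at Day 28, and ASNS from 541 to 24.3 and 185.

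The days between showed when these changes took place. From Day 3 to Day 7, ALB went from 11500 ± 570 to 18900 ± 1740 CPM and AFP from 12200 ± 185 to 19200 ± 1000. In that step 26 of 29 plasma protein genes rose and none fell (median 0.65, adjusted p = 3.46e-37), as did 9 of 15 phase I genes with none lower (median 0.83, adjusted p = 2.1e-06). HAL rose by 2.63 ± 0.19, G6PC by 2.37 ± 0.22 and the peptidase gene MEP1A by 2.26 ± 0.11, while IGFBP2 fell by 0.86 ± 0.14, SIVA1 by 0.82 ± 0.15 and the glucose transporter SLC2A3 by 0.84 ± 0.22. The SLC2A3 call was lost without Day 7 replicate 3 (-0.74, adjusted p = 0.0617). In all 1312 genes were higher and 1081 lower, and scaling by library size alone turned this split to 1065 higher and 1637 lower. The count of 2393 fell to 1579 without Day 3 replicate 1 and to 1547 without Day 7 replicate 3, and was 3600 in a fit of these groups alone.

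From Day 7 to Day 10, 18 of 29 hypoxia response genes rose and none fell (median 0.66, adjusted p = 2.21e-22). Glycolysis had 12 of 17 higher and none lower (median 0.46, adjusted p = 1.17e-11), and the p53 response had 15 of 24 lower and none higher (median -0.41, adjusted p = 4.88e-10). SLC2A3 rose by 2.06 ± 0.22, its close paralog SLC2A14 by 1.99 ± 0.19 and IGFBP1 by 1.77 ± 0.079. CAPN3 fell by 1.93 ± 0.13, TRIM73 by 1.66 ± 0.19 and NUPR1, a stress-induced gene, by 1.56 ± 0.15. In this step 1718 genes were higher and 1664 lower by edgeR, and scaling by library size alone gave 1487 higher and 1859 lower.

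The step from Day 10 to Day 14 changed most genes, 2968 higher and 2999 lower, with a median absolute log2 difference of 0.363 against 0.199 to 0.232 in the other consecutive steps. Scaling by library size alone gave 3376 higher and 2628 lower. All 25 ATF4 response genes rose (median 1.67, adjusted p = 1.36e-35), and ASNS went from 26.0 ± 1.65 to 165 ± 3.83 CPM. All 29 DNA replication genes fell (median -2.09, adjusted p = 7.09e-36), as did 23 of 24 mitosis genes with none higher (median -2.15, adjusted p = 2.05e-30). MKI67 went from 134 ± 2.96 to 29 ± 6.07 CPM. Of 23 cholesterol genes 22 fell and none rose (median -1.85, adjusted p = 3.82e-38). GPR83 rose by 4.03 ± 0.33, MAT2A, which makes the methyl donor S-adenosylmethionine, by 3.15 ± 0.072 and URB2 by 3.13 ± 0.62, the last with a spread of 29.9 ± 22 CPM at Day 14 and a call that was lost in a fit of these groups alone (adjusted p = 0.0534). RRM2 fell by 3.44 ± 0.27, FAM111B by 3.10 ± 0.22 and the dUTPase gene DUT by 2.93 ± 0.29.

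From Day 14 to Day 21, 19 of 20 chaperones of the endoplasmic reticulum rose and none fell (median 1.16, adjusted p = 6.19e-57), with CRELD2 at 2.46 ± 0.12, SDF2L1 at 2.37 ± 0.13 and MANF at 2.32 ± 0.12. Hypoxia response genes had 13 of 29 lower and 2 higher (median -0.43, adjusted p = 6.19e-07), and acute phase proteins 8 of 14 lower and none higher (median -0.52, adjusted p = 1.85e-07). CYP24A1 fell by 2.42 ± 0.31, the WNT inhibitor DKK1 by 2.16 ± 0.30 and GPCPD1 by 2.03 ± 0.13. In this step 1718 genes were higher and 1571 lower, and scaling by library size alone gave 1463 higher and 1870 lower. From Day 21 to Day 28, 11 of 25 ATF4 response genes rose and none fell (median 0.25, adjusted p = 1.73e-06), 10 of 29 hypoxia genes rose and 3 fell (median 0.40, adjusted p = 2.56e-06), and 19 of 29 DNA replication genes fell and none rose (median -0.56, adjusted p = 3.4e-09; adjusted p = 0.183 with an estimated correlation). IGFBP1 rose by 1.95 ± 0.079, HAVCR1 by 1.71 ± 0.10 and the hypoxia gene NDRG1 by 1.53 ± 0.16, while ODAM fell by 2.50 ± 0.15, S100A4 by 2.02 ± 0.31 and the histone gene H2BC3 by 1.94 ± 0.25. In that step 1240 genes were higher and 1724 lower, scaling by library size alone gave 1661 higher and 1324 lower, and a fit of these groups alone called 1865 genes in place of 2964. These list tests of the consecutive steps were added after the data had been seen and form a family of their own.

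Against the monolayer, the genes with the largest rises included FAM111A (6.03 ± 0.17) and ERP27 (5.91 ± 0.15) at Day 7, the histone genes H2BC14 (6.30 ± 0.32), H2AC14 (6.2 ± 0.31) and H1-5 (6.11 ± 0.35) at Day 10, APOL1 (5.97 ± 0.69), G6PC (5.05 ± 0.31) and the manganese transporter SLC30A10 (4.86 ± 0.093) at Day 14, and LACTBL1 (5.50 ± 0.21), APOL1 (5.44 ± 0.70) and FGA (5.25 ± 0.098) at Day 21. The largest falls were in AREG (-8.69 ± 0.64), RGCC (-8.04 ± 0.43) and ATP6V0D2 (-7.73 ± 0.37) at Day 7 and in AREG (-7.66 ± 0.60), AHNAK2 (-7.66 ± 0.39) and RGCC (-7.54 ± 0.42) at Day 10. At Day 14 they were in AHNAK2 (-7.55 ± 0.39), ATP6V0D2 (-7.42 ± 0.37) and EREG (-7.29 ± 0.44), and at Day 21 in EREG (-8.55 ± 0.50), ATP6V0D2 (-8.19 ± 0.39) and DUSP5 (-7.66 ± 0.39). Higher and lower genes numbered 4984 and 4735 at Day 7, 4936 and 4682 at Day 10, 4779 and 4405 at Day 14, and 4849 and 4327 at Day 21. Scaling by library size alone gave 5531 and 4154, 5402 and 4195, 5535 and 3663, and 5498 and 3715. In all 6538 genes were called in one direction at all 6 days, 3370 higher and 3168 lower.

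Comparing both ends of the time course, 7382 genes were called in the same direction against the monolayer at Day 3 and at Day 28, 3839 higher and 3543 lower, and 484 in opposite directions. Independent lists of these sizes would share 1909 higher and 1628 lower genes. Simulated unchanged groups set against the same monolayer libraries shared 0 calls in 20 simulations, but with no change almost no gene is called, so this 0 sets no bar for the shared calls. The 3 monolayer libraries do not make 2 sets of at least 2, so part of the excess over independent lists may come from the shared libraries. Across genes, which are not independent replicates, the log2 fold changes at Day 3 and Day 28 correlated at r = 0.797, against 0.49 in the simulations (0.456 to 0.537), with a covariance of 2.30 against 0.0375. The difference in covariance, 2.26, lies beyond what the shared libraries add in the simulations. Of the genes changed at Day 3, 4852 moved back between Day 3 and Day 28, 2531 of them higher and then lower and 2321 lower and then higher, where independent lists would share 1496 and 1376. The simulations gave 0, again for want of calls, and part of this excess may come from the shared Day 3 libraries. At Day 28, 1369 of these were no longer called against the monolayer and 484 were called on its other side. A further 1446 moved on in the direction of their first change. The correlation of the first change with the later one, -0.503, was close to the simulated -0.489, where the only link is the Day 3 libraries that both use, while its covariance was -1.01 against -0.0374.

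The list tests in this paragraph did not pass. At Day 3 against the monolayer, hypoxia response genes went both ways (12 of 29 higher and 11 lower, median 0.06, adjusted p = 0.961), as did glycolysis (9 of 17 higher and 4 lower, median 0.55, adjusted p = 0.305), the p53 response (10 of 24 higher and 9 lower, median 0.22, adjusted p = 0.511) and the interferon response (4 of 15 higher and 4 lower, median 0.23, adjusted p = 0.995). For hypoxia and interferon the test's direction was down with a mean above 0, and for p53 the mean was below 0. Gluconeogenesis and glycogen had 10 of 15 higher and 4 lower (median 0.58, adjusted p = 0.445), epithelial junctions and keratins 8 of 22 higher and 12 lower (median -0.39, mean 0.07, adjusted p = 0.161), and NF-kB and chemokines 1 of 12 higher and 8 lower (median -0.82, adjusted p = 0.123). At Day 28 against the monolayer the adjusted p was 0.414 for hypoxia, 0.612 for glycolysis (median 0.10, mean -0.56), 0.961 for interferon (median 0.02, mean -0.07), 0.0996 for gluconeogenesis, 0.0837 for epithelial junctions (median -0.65, mean 0.02) and 0.0883 for NF-kB and chemokines. Among markers of other liver cell types, 2 of 12 stellate cell and fibroblast markers and 4 of 12 endothelial markers were measured, too few to test. Of 14 macrophage and leukocyte markers 5 were measured, and 3 of these rose at Day 3 with none lower (median 1.02, adjusted p = 0.119). Cholangiocyte markers at Day 3 had 3 of 8 higher and 4 lower (median 0.13, adjusted p = 0.995).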

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

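Of the tests in this part, the one on scaling of the cell cycle genes, the one on the ATF4 and DNA replication lists, and the look for batch labels were chosen only after the result was seen.

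The effects of Day 3 and of Day 28 against the monolayer differed, by the test of Day 28 against Day 3, in 16 gene lists. With an estimated correlation 12 of these calls were lost. Those that held were the ATF4 response, chaperones of the endoplasmic reticulum, acute phase proteins and cholangiocyte markers. The median differences in log2 fold change were 1.86 for the ATF4 amino acid response, 1.37 for chaperones of the endoplasmic reticulum, 0.79 for acute phase proteins, 0.47 for immediate early genes and 0.20 for hepatocyte plasma proteins. They were -2.73 for metallothioneins, -2.23 for mitosis, -2.15 for DNA replication, -1.21 for cholesterol synthesis, -0.92 for iron handling, -0.85 for fatty acid and triglyceride synthesis, -0.74 for extracellular matrix, -0.72 for both glycolysis and cholangiocyte markers, -0.61 for actin and focal adhesion and -0.36 for oxidative phosphorylation.

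Among the named genes, 14 were called on one side of the monolayer at Day 3 and on the other at Day 28. SLC17A2 went from -2.52 to 2.66, a difference of 5.17, HAL from -1.96 to 2.95 (4.91), IGFBP1 from -3.47 to 1.23 (4.70), TAT from -2.00 to 1.77 (3.76), CYP7A1 from -1.47 to 1.61 (3.08), ITIH3 from -2.01 to 0.71 (2.72) and HYOU1 from -1.94 to 0.23 (2.16). S100A4 went from 1.53 to -3.89 (-5.42), MT2A from 1.61 to -1.54 (-3.15), AGPAT2 from 0.68 to -1.71 (-2.39), ANXA4 from 1.48 to -0.57 (-2.06), ACTB from 0.63 to -0.77 (-1.39), NDUFA1 from 0.44 to -0.55 (-0.99) and ETFA from 0.18 to -0.51 (-0.69). CYP7A1 has few counts, and its call at Day 3 was lost without monolayer replicate 1 (adjusted p = 0.0837) or Day 3 replicate 3 (adjusted p = 0.0632).

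The first pattern weighed is that mitosis and DNA replication genes were lower in the monolayer than in Day 3 spheroids. The choice among 3 scalings does not account for it, since the lowest median of the 53 genes over them was 4.44. Library size alone shifted the median of all genes by only 0.217, so these scalings could not have removed the pattern. A trend with transcript GC content and length is excluded as the whole cause, since it left a median of 4.08 (the content of the probes themselves was not known). A candidate explanation is a stress state of the monolayer in which ATF4 targets and the cell cycle move apart: in 4 of 6 steps both the ATF4 and the DNA replication list were called, and in all 4 in opposite directions, but with an estimated correlation both were called in only 1, from Day 10 to Day 14 (adjusted p for DNA replication 0.105 at Day 3, 0.0987 from Day 7 to Day 10 and 0.183 from Day 21 to Day 28). Among the 4 steps are Day 3 against the monolayer, the pattern itself, and Day 7 to Day 10, with an ATF4 median of only -0.05. The step test replaced an earlier form on the signs of the medians, in which ATF4 medians of 3 steps lay within 0.06 of 0, so it is a hypothesis from the data it was found in. At Days 14 and 28 the ATF4 median against the monolayer was only -0.22 and -0.25. Mitosis stayed at 2.79 and 2.63 and DNA replication at 1.85 and 1.39, well above the monolayer although the ATF4 median was near its level. At Day 21 the ATF4 median was lower, at -0.79, and mitosis (3.06) and DNA replication (1.96) were higher, so the lists did move apart there. The late days thus go both ways on this explanation. Cell density, medium age and collection time of the monolayer are not in the labels and stay open.

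The second pattern is the break between Day 10 and Day 14, the largest consecutive change. A trend with transcript GC content and length explained 1.78% of its variance, so that trend accounts for little of the break. The content of the probes themselves was not known, so an effect of the probes could not be tested. Across genes, the change correlated at r = 0.499 (Spearman 0.446) with the monolayer minus Day 3 difference, which shares no library with it. The steps before and after gave -0.0437 and -0.0297, and the last step 0.242. Part of the change may thus be a partial return toward the monolayer profile, without showing why. On the second component the step went away from the monolayer, which lay at 29.15, from 26.31 at Day 10 to -27.34 at Day 14. Much of the break is therefore not a return. A library or sequencing batch that split Days 3 to 10 from Days 14 to 28 cannot be told apart from age, because 0 libraries have a batch, plate, lane or date in their labels.

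For the 12 comparisons of 3 against 3 libraries, 1 of the 10 splits, the real one, gave as many genes, and the splits are too few for a share under 0.05. The real splits, fitted on their own libraries, called 9659, 9623, 9411, 9019, 8899 and 8664 genes for Days 3 to 28 against the monolayer, 3600, 3743, 5771, 2826 and 1865 for the consecutive steps and 7135 for Day 28 against Day 3, while the highest other split called 0 in each. For the change among spheroid days, the real groups gave 9378 genes and the highest of the other splits among 100 gave 1051, with a median of 0. Shuffled groups mix libraries of different days, which widens their spread and lowers their counts. A culture or batch shared by the libraries of a day is not excluded by this. For the genes shared by Day 3 and Day 28 the real groups gave 7348 and the highest other split 1919. For those that moved back the values were 4828 and 1919, each among 100 splits. The median of the other splits was 0 for shared genes and for genes that moved back. These splits thus show that libraries of a group resemble each other more than those of other groups, but set no bar for sharing or moving back.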

How the results depend on the processing

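The list tests of the other 9 comparisons, and the closer look at Day 28 without its replicate 1, were chosen only after the data were seen, and the remaining alternatives were planned. No called gene was called in the opposite direction under any alternative. Genes that changed sign and lost their call were not counted. With library size alone, 8874 of 9627 calls at Day 3 against the monolayer were kept. No called list of the 3 main comparisons turned its direction under the alternatives run for lists (not run with no filter, DESeq2 or a fit of only the groups compared). The balance of higher and lower genes did turn, with library size alone in all 5 consecutive steps (for Day 7 against Day 3 from 1312 and 1081 to 1065 and 1637), and in some comparisons near balance under other settings. With RLE size factors, library size alone, no filter, DESeq2 or the replicate block, every count of called genes stayed within 1.5 times its value, and all 245 named-gene results kept their direction and their side of the threshold except 1, AFP at Day 28 against Day 3, which passed with no filter (-0.24). Most of these genes were picked for large called changes, which favours keeping the call. A 2-fold minimum lowered the counts, by its construction, to 5613, 5633, 5692, 4882, 4850 and 4652 genes against the monolayer at Days 3 to 28, to 227, 225, 1361, 312 and 299 in the consecutive steps, to 2378 for Day 28 against Day 3, to 2826 for any change among spheroid days, to 3586 for genes shared by Day 3 and Day 28 and to 1517 for those that moved back. In a fit of only the groups compared, Day 7 against Day 3 gave 3600 genes and Day 28 against Day 21 gave 1865. Replicate pairs had a chi-square per degree of freedom of 5.68 to 7.69 at Day 3. It was 14.2 to 28.2 at Day 21 and 12.1 to 29.7 at Day 28, highest in the pairs with Day 28 replicate 1. The main fit shares 1 estimate of spread per gene over all groups. Whether this unequal spread caused the shifts in counts was not tested. Of 102 list tests 57 were called, and 17 of these were also called with an estimated correlation. Fry, which asks another question, called 91 of the 102. Scaling by library size alone shifted the median log2 fold change of all genes by 0.217 at Day 3 and 0.215 at Day 28 against the monolayer, and ended the calls of the actin list at Day 3 (-0.26) and the ATF4 list at Day 28 (-0.03).

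Leaving out each library in turn gave 9242 to 9403 genes at Day 3 against the monolayer, 9353 to 9509 at Day 7, 9297 to 9438 at Day 10, 8801 to 8969 at Day 14, 8799 to 9018 at Day 21 and 8670 to 8866 at Day 28. For the steps it gave 1547 to 2086 from Day 3 to Day 7 (1579 without Day 3 replicate 1 and 1547 without Day 7 replicate 3), 2607 to 3368 to Day 10, 5211 to 5678 to Day 14, 2616 to 3008 to Day 21 and 2026 to 3399 to Day 28. It gave 6831 to 7185 for Day 28 against Day 3, 9166 to 9484 for any change among spheroid days, 7004 to 7276 shared genes, 4511 to 4816 that moved back, and 56 to 57 list tests. Without Day 28 replicate 1, the shallowest library, Day 28 gave 8866 genes against the monolayer and 7185 against Day 3. Of single results, ALB, CPS1, CYP7A1, SLC2A3, AFP and the extracellular matrix and ATF4 lists changed call when 1 library was left out, as given beside them. Depth limits CYP3A4 and CA9 against the monolayer, whose libraries held 6 and 4 of their counts.

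The replicate numbers were not taken as pairs in the main fit. Same-numbered libraries of different groups correlated at a mean r of 0.0176 (-0.0599 to 0.0991), and differently numbered ones at -0.00878. Of the same-numbered pairs 0 of 63 were over 0.1, and of the others 0 of 126, so this cutoff does not tell them apart. Yet 16 of 21 libraries correlated best with their own number, which points to some weak structure shared by replicate number. With the replicate block the counts were 9653, 9749, 9641, 9217, 9208 and 9113 against the monolayer at Days 3 to 28, 2613, 3601, 6061, 3499 and 3203 in the steps, 7419 for Day 28 against Day 3, 9452 for any change, 7424 shared and 4874 moved back, with 57 list tests called, and it changed no call of a named gene or list.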

Other observations

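The gene families in this part were chosen after the data were seen, and all its values are descriptions with no test of the family as a whole.

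Replication-dependent histone genes moved with the cell cycle lists. Of 60 measured, 53 were higher and 3 lower at Day 3 than in the monolayer (median log2 fold change 3.29), 50 fell and 1 rose from Day 10 to Day 14 (median -2.04), and 50 fell and 3 rose from Day 3 to Day 28 (median -2.13). H2AC4 rose by 5.80 ± 0.31 and H2AC17 by 5.54 ± 0.40 at Day 3, though near-identical copies can share counts. Genes for cytosolic ribosomal proteins went the other way: 62 of 76 were lower and 7 higher at Day 3 (median -0.90), with RPL34 at -1.62 ± 0.13 and RPL26 at -1.56 ± 0.075. From Day 3 to Day 28, 64 rose and 2 fell (median 0.79), and at Day 28 the median against the monolayer was -0.04, or 0.18 with scaling by library size alone, so its sign depends on the scaling.

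Cytosolic aminoacyl-tRNA synthetases, none of which is in the ATF4 list, followed that list. At Day 3, 16 of 17 were lower and 1 higher (median -1.26), with CARS1 at -2.66 ± 0.12 and SARS1 at -2.60 ± 0.078. From Day 10 to Day 14, 14 rose and 1 fell (median 0.72), and from Day 3 to Day 28, 15 rose and none fell (median 0.81), WARS1 by 1.86 ± 0.077. S100 genes had 8 of 13 lower and 3 higher at Day 3 and 11 lower and none higher at Day 28 against the monolayer (median -2.54). Keratin genes had 7 of 10 lower and 1 higher at Day 3 (median -2.08) and 9 lower and none higher at Day 28 (median -3.23), with KRT80 at -4.39 ± 0.31 at Day 3. Proteasome subunits went both ways, with 15 of 37 higher and 11 lower at Day 3 and a median of 0.02, which was -0.01 with RLE size factors and 0.23 with scaling by library size alone.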
